A study of Mus musculus with 4 samples.

How the data were processed

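Per the file headers and the submitters' processing notes, the deposited matrices hold unnormalized UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) per gene and cell barcode, with 27998 gene identifiers and symbols. The labels name Chromium Single Cell 3' v2 chemistry, Cell Ranger, STAR, bcl2fastq and the mm10 genome build. They give no tool versions, no annotation release, no filter used to call barcodes as cells, and no statement of whether mice were pooled. Of the identifiers in the files, 27645 were found in GENCODE vM21 (GRCm38, the assembly mm10 stands for), which gave the coordinates.

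All barcodes of the 4 libraries were clustered together without batch correction. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet was run within each library at an expected doublet rate of 0.06, and the 80 barcodes it called (0.507% of those passing the filter) were left out, which is far below that expected rate, so most doublets probably stayed in. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes within libraries were taken without mitochondrial and ribosomal genes and without any gene of the gene lists, so that the listed genes did not define the clusters. Genes outside the lists that were named for their ratio were not left out. They could therefore shape the clusters across which they were compared. Leiden clustering at resolution 1 used 30 principal components and 15 neighbours with seed 1.

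Clusters were named from 232 marker genes of 22 cell classes fixed before the data were examined. A class name needed at least 3 markers with a log2 fold of at least 1 and a mean marker log2 fold of at least 0.5. Where another class had at least as many of its markers among the 10 leading genes, the cluster stayed unnamed. Clusters with at least 5 cell cycle genes among those 10 also stayed unnamed. Every name ends in "-like" because it rests on RNA alone. A class is the union of its clusters, so a class can be held by different clusters in different libraries.

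With 1 library per group, cells are not replicates and no test between groups was run. Shares of cells carry exact Clopper-Pearson 95% intervals. Because the labels say that Tim4+ Kupffer cells were set to 20% of the sorted cells, shares were taken among kept cells other than Kupffer-like cells. Within a class, UMIs were summed over the cells of a library and given as CPM (the gene's UMIs scaled to a common total of all UMIs of the class), with exact Poisson 95% intervals. Ratios of libraries carry the exact conditional binomial 95% interval. Where a gene had 0 UMIs in a library, the ratio was bounded with a floor of 3 counts and is given as "at least". All intervals and floors cover counting error only. Expression was compared in classes with at least 50 cells in both libraries, in 3 contrasts: IL-4c over PBS in naive mice, IL-4c over PBS after CCl4, and CCl4 over naive among PBS libraries.

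Genes were named by a rule fixed before the data were examined. For each class and contrast these were the 12 genes with the highest and the 12 with the lowest ratio, ranked by the interval bound nearest to 1, among genes with at least 50 CPM and at least 20 UMIs in the higher library. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and class marker genes were left out. Genes under 5% of their level in another class of at least 20 cells in the same library were left out too, as possible free RNA. Retnla, Chil3, Arg1, Mrc1, Mki67 and Top2a were always given, with up to 4 members of each gene list that have the largest absolute log2 ratio.

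The 17 gene lists, fixed before the data were examined, covered IL-4 response, DNA replication and S phase, mitosis and G2/M, pro-apoptotic and anti-apoptotic genes, Kupffer cell maturation, efferocytosis and scavenging, macrophage transcription factors, matrix remodelling and growth factors, inflammatory cytokines, interferon response, antigen presentation, lipid handling, iron and haem handling, glycolysis, oxidative phosphorylation with the TCA cycle, and dissociation stress with immediate early genes. Of all the listed and marker genes, 15 were not in the files. A list's value is the median log2 ratio of its members with at least 20 UMIs over both libraries, and members without UMIs in 1 library entered at their bound. The interval of a median came from 1000 Poisson redraws of the counts. Each median was placed among 10000 random lists of equal size drawn from the 100 genes nearest in mean expression to each member. That percentile describes these libraries and is not a test. Members were counted as at least 2-fold higher, at least 2-fold lower or in between, a rule of size.

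Cycling cells were to be counted as cells with at least 3 UMIs of the mitosis and G2/M list after thinning each cell to 1000 UMIs. Cells of the planned background class, neutrophil-like cells, were not found, so plasmacytoid DC-like cells served as background. That choice was made after the data were seen. In them the planned count ranged from 12.7% to 22.4%, so a stricter count was added after the data were seen: cells with at least 1 UMI of 12 mitotic genes (Mki67, Top2a, Birc5, Ube2c, Cdk1, Ccna2, Ccnb1, Ccnb2, Nusap1, Cenpf, Tpx2 and Prc1) among 1000 UMIs. A clustering added at the same time left out 566 genes whose expression followed the G2/M list across cells (correlation above 0.15), so that cycling cells stayed with their own type.

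The interval and the naming rule were tried on simulated counts with known ratios at the depth of the Kupffer-like cells. The counts were drawn from the Poisson model that the interval assumes, so its coverage was largely set in advance. Clustering, class naming, the free RNA rule and variation between cells or libraries beyond counting error were not simulated. In the simulated naive pair of 10474 genes, the interval lay on the right side of 1 for 79.1% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold. It covered 1 for 95.7% of the 8496 unchanged genes, and all 24 genes named by the rule were changed ones. The analysis used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.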

Results

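RNA of single cells was measured in leukocytes sorted from the livers of male C57BL/6Crl mice as CD45+CD19-CD3-CD31-NK1.1-, a gate that keeps mainly myeloid cells. The 4 libraries stood for 4 groups, 1 library per group. Mice were left naive or given CCl4, a chemical that injures hepatocytes, and 24 h later received IL-4c (the IL-4 preparation of the labels, taken here as an IL-4 complex) or PBS into the blood. Livers were taken 48 h after that. The naive PBS library held 4624 barcodes and 22713524 UMIs, and the naive IL-4c library held 3522 barcodes and 24464347 UMIs. The CCl4 PBS library held 3987 barcodes and 47915417 UMIs, and the CCl4 IL-4c library held 4468 barcodes and 42415225 UMIs. After filtering, 15706 cells in 25 clusters remained, with median depths of 4451, 6488.5, 9913 and 8223.5 UMIs in the order naive PBS, naive IL-4c, CCl4 PBS and CCl4 IL-4c, which is the order of all series of 4 values here. With 1 library per group no difference could be set against the spread between replicates, so every difference is one between 2 libraries, and intervals (95%) cover counting error only.

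The comparison of cell classes asked how IL-4c and injury related to the make-up of the hepatic myeloid pool. In naive livers given IL-4c, patrolling monocyte-like cells, which survey the vessel wall, and monocyte-derived macrophage-like cells were scarcer than after PBS. cDC2-like cells, dendritic cells that prime CD4 T cells, were more frequent. After CCl4, monocyte-derived macrophage-like cells were the largest class whether PBS or IL-4c was given, but the cells lay in different clusters. Plasmacytoid DC-like cells, a source of type I interferon, were a smaller share after CCl4 than in naive livers, and less so when IL-4c was given. All of these are shares of a fixed total, so a class that grows lowers the shares of the others.

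Patrolling monocyte-like cells made up 7.0% of the 3743 cells other than Kupffer-like in the naive PBS library (6.20 to 7.87%) and 1.04% of 2309 in the naive IL-4c library (0.667 to 1.54%), a share 6.73-fold lower (4.43 to 10.7). With the same classes, among cells above a common floor of 3540 UMIs, the share was 12.8-fold lower (5.25 to 40.4). Monocyte-derived macrophage-like cells made up 9.14% (8.23 to 10.1%) against 1.13% (26 cells, 0.737 to 1.65%), 8.11-fold lower (5.44 to 12.6). cDC2-like cells made up 10.4% and 22.4%, a ratio of 2.16 (1.89 to 2.47), and they came mostly from cluster 6 after PBS and from cluster 10 after IL-4c. cDC1-like cells numbered 412 with PBS and 293 with IL-4c, and the interval of the ratio of their shares included 1. The plasmacytoid DC-like share was 1.64-fold lower with IL-4c. Kupffer-like cells, whose Tim4+ part the sort had set to 20%, were 13.7, 26.2, 18.4 and 16.9% of all kept cells and were not compared as shares. The lowest UMI count of a deposited barcode was 1422, 1766, 3540 and 2700, and 28.5% of kept naive PBS cells lay under the highest of these, so shares of cells with little RNA also reflect depth.

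After CCl4, monocyte-derived macrophage-like cells made up 53.7% of 3202 cells with PBS (52.0 to 55.5%) and 55.2% of 3585 with IL-4c (53.5 to 56.8%), a ratio of 1.03 (0.962 to 1.10). Cluster 8 held 1675 of these 1720 cells with PBS, and cluster 9 held 1938 of 1978 with IL-4c. A further cycling cluster with macrophage-like RNA, cluster 24, held 263 cells with PBS and 10 with IL-4c, and counted together clusters 8, 9 and 24 were 61.5% and 55.3%. Against naive PBS mice, the class was 5.88-fold more frequent after CCl4 (5.23 to 6.62), a log2 share ratio of 2.56 that ran from 0.942 with each library clustered on its own to 6.52 with the gene lists among the clustering genes. In naive PBS mice 302 of the 342 cells were in cluster 13, and clusters 8 and 9 alone made up 1.07% there and 53.3% after CCl4. cDC2-like cells were at 8.18% with PBS and 12.9% with IL-4c (ratio 1.58, 1.35 to 1.84), and plasmacytoid DC-like cells at 1.97% and 6.11% (ratio 3.11, 2.34 to 4.18). Among PBS libraries, the plasmacytoid DC-like share was 10.8-fold and the cDC1-like share 3.39-fold lower after CCl4 than in naive mice. Patrolling monocyte-like cells numbered 7 after CCl4, a share 32.0-fold lower than in naive PBS mice and 14.1-fold lower above the common floor. Clusters 8, 9 and 24 together went from 1.10% to 61.5% between these PBS libraries, which by itself lowers every other share. Whether these classes lost cells per liver was not tested.

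**Figure D1:**
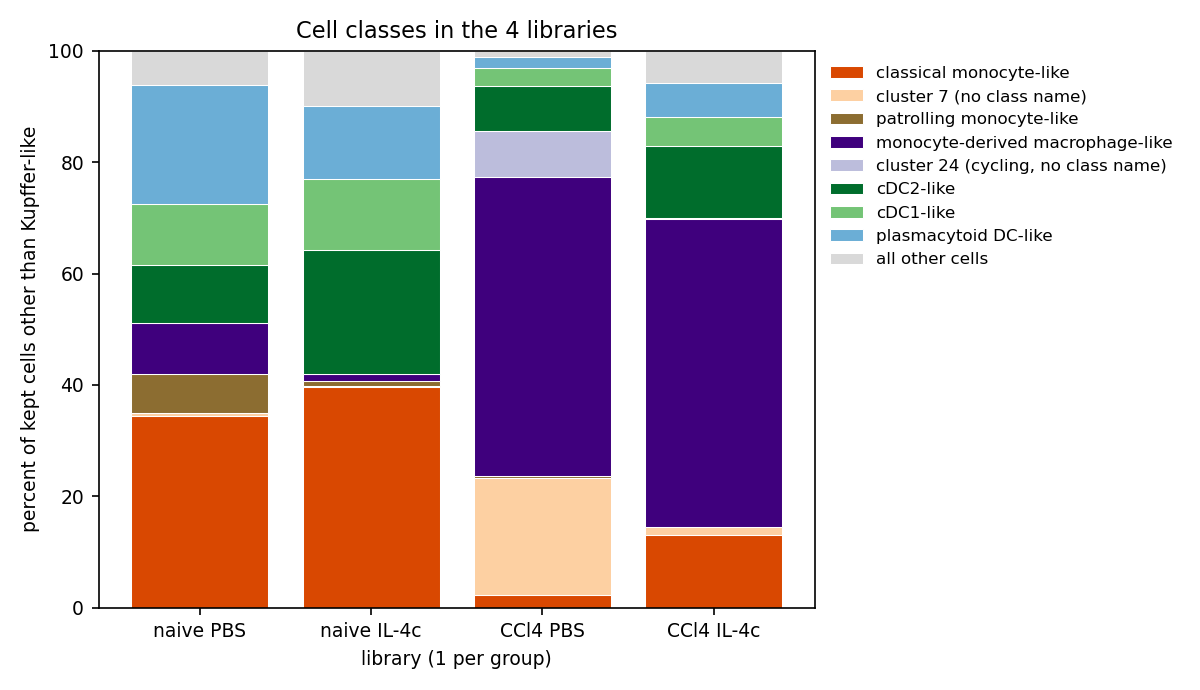
Bars show the percent of kept cells other than Kupffer-like cells (y axis) in each class for the 4 libraries (x axis), with clusters 7 and 24 drawn apart from the named classes. Monocyte-derived macrophage-like cells take 53.7% and 55.2% of the CCl4 libraries against 9.14% and 1.13% of the naive ones.

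For classical monocyte-like cells, recruited from blood, the direction of the IL-4c share against the PBS share turned with the clustering in naive and in CCl4-treated mice, while the share after CCl4 was lower than in naive PBS mice under every alternative run (log2 -8.11 to -0.582). They made up 34.5% and 39.6% of the naive libraries (PBS, IL-4c) and 2.31% and 13.1% of the CCl4 libraries. Cluster 7, with S100a8, S100a9, Lcn2 and Vcan among its leading genes, stayed unnamed between the monocyte and neutrophil markers although its CCl4 PBS cells had the monocyte genes Ccr2 at 937 CPM and Ly6c2 at 925, against 971 and 1453 in naive PBS cells of cluster 2, and no UMI of the neutrophil gene Ly6g, which had none in cluster 2 either. It made up 0.454, 0.173, 21.1 and 1.51%. Counted with the classical monocyte-like cells, it turned the CCl4 pair to 23.4% with PBS and 14.6% with IL-4c. At resolution 2 the log2 ratio of the IL-4c share to the PBS share was -1.60 in naive mice and -0.795 after CCl4. The clusters also differed, since 789 of the 1292 naive PBS cells were in cluster 5 and 837 of the 914 naive IL-4c cells in cluster 11.

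The comparison of Kupffer-like cells in naive mice asked how resident liver macrophages, the main phagocytes of the sinusoid, responded to IL-4c without injury. Kupffer-like cells of IL-4c mice had far more RNA for Retnla, a secreted protein typical of IL-4-activated macrophages, for the arginine transporter Slc7a2 and arginase Arg1, which feed arginine into ornithine, and for the eosinophil-associated ribonucleases Rnase2a and Ear2. RNA for Ccl24, a chemokine that attracts eosinophils, and for the chitinase-like Chil3 was also higher. RNA for the scavenger receptor Marco, the complement regulator Cd55, the Toll-like receptor signalling brake Irak3, lysozyme (Lyz2) and the interferon-induced chemokine Cxcl10 was lower. Genes of DNA replication, mitosis and mitochondrial respiration stood higher as groups, and inflammatory genes stood lower.

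Retnla (ENSMUSG00000061100, GRCm38 chromosome 16, 48842551 to 48844461) was at 18610 CPM (UMIs scaled to a common class total) with IL-4c and 2.23 with PBS (8 UMIs), a log2 ratio of 13.02 (12.05 to 14.24). Arg1 (chromosome 10, 24915221 to 24927484) was at 433 against 2.79 (log2 7.28, 6.40 to 8.34), and Slc7a2 at 679 against 3.63 (log2 7.55, 6.77 to 8.46). Chil3 (chromosome 3, 106147554 to 106167564) was at 113 against 10.1 (log2 3.49). Ear2 was at 3776 against 322 and Ccl24 at 4224 against 416. Mrc1, the mannose receptor (chromosome 2, 14229392 to 14332057), differed little (log2 0.11). Postn (log2 6.28), a matrix protein, and the mitochondrial protein gene Chchd10 (3.86) were also higher. Marco (chromosome 1, 120474538 to 120505024) was at 121 against 2709 (log2 -4.48), Lyz2 at 883 against 7428 (log2 -3.07), Cd55 at log2 -4.53, the formyl peptide receptor gene Fpr2 at -3.40 and the inhibitory lectin gene Siglece at -3.26. Of the 821 cells with IL-4c, 771 were in cluster 22, and of the 594 with PBS, 536 were in cluster 0. Some of these differences were shared by all 5 classes compared in naive mice, plasmacytoid DC-like cells included. There Retnla, Rnase2a, Ear2 and Igf1 were at least 2-fold higher with IL-4c, and 14 genes, among them Marco, Lyz2, Ccl5, Il1rn, Cxcl9 and Ly6i, were at least 2-fold lower. In plasmacytoid DC-like cells the levels were small, with Retnla at 506 and Marco at 3.83 against 26.1, near the background that free Kupffer-like RNA gives, so a shared shift does not tell which classes express these genes.

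**Figure D2:**
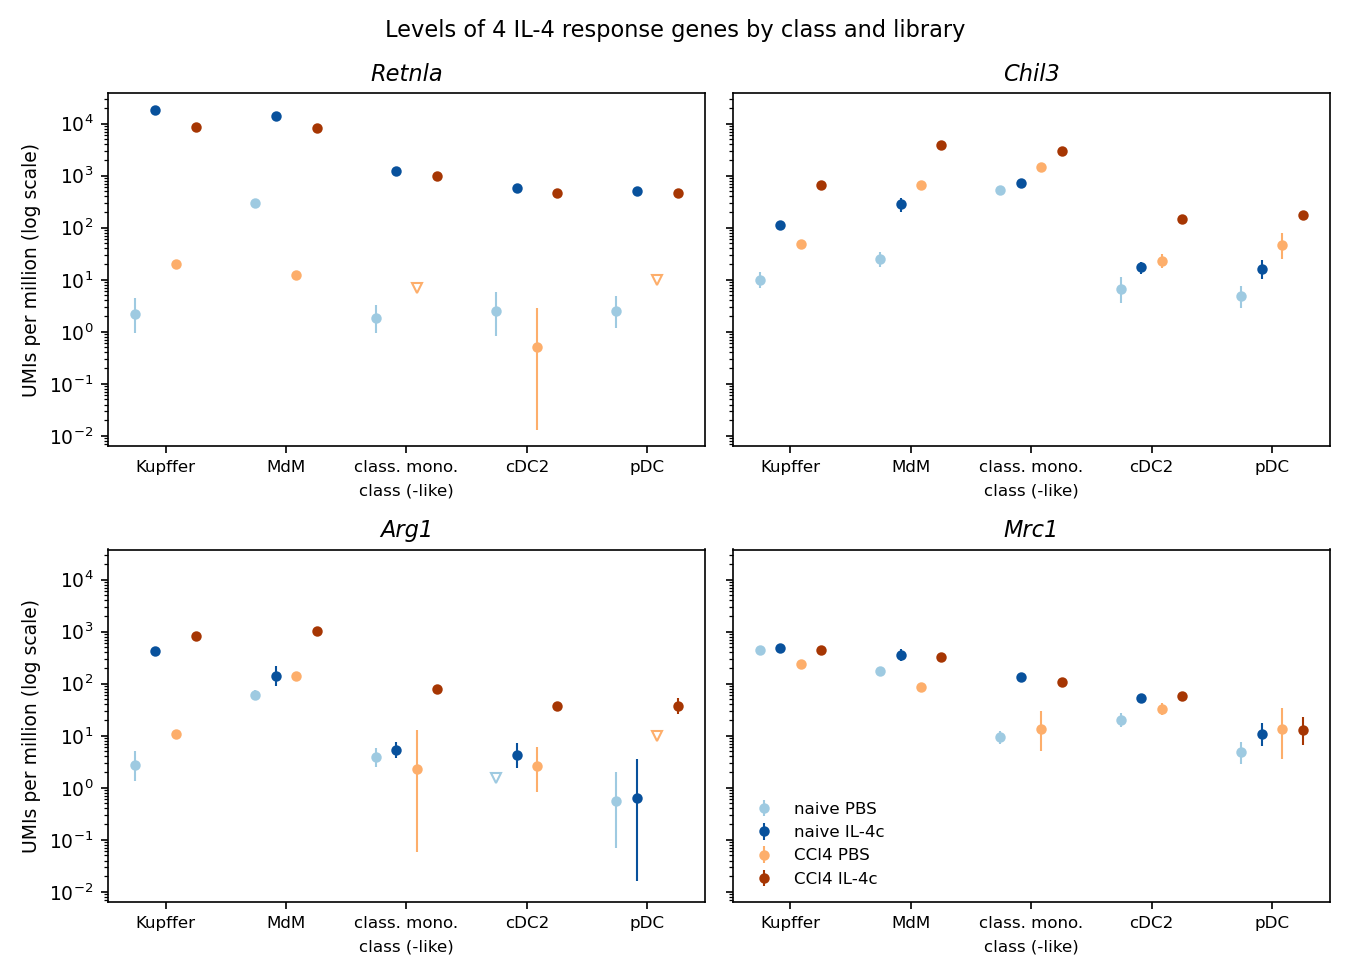
Levels of Retnla, Chil3, Arg1 and Mrc1 in CPM (y axis, log scale) in 5 cell classes (x axis) of the 4 libraries, with bars for the 95% Poisson interval and open triangles at the 3-count limit where no UMI was counted. Retnla in Kupffer-like cells is at 18610 in the naive IL-4c library and 2.23 in the naive PBS library, with 506 and 2.55 in plasmacytoid DC-like cells.

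Among gene lists in these Kupffer-like cells, the IL-4 response list had a median log2 ratio of 1.63 (1.38 to 2.07), with 14 of 24 members at least 2-fold higher and 0 lower, at percentile 100 of expression-matched random lists. With every member of at least 1 UMI counted it was 0.951. Oxidative phosphorylation and TCA cycle genes had a median of 0.98 (Cox7b 1.34, Aco2 1.20; percentile 100), DNA replication and S phase genes 0.80 (Rrm1 1.30, Rrm2 1.13; percentile 100) and mitosis and G2/M genes 0.67 (2810417H13Rik 1.70, Top2a 0.97; percentile 100), the last 2.27 at resolution 2. Inflammatory cytokine genes had a median of -1.05, with 15 of 29 at least 2-fold lower (Ccl5 -2.89, Cxcl10 -2.85), while the chemokines Ccl9 (2.39) and Ccl6 (1.78) were higher. Anti-apoptotic genes (-0.58; Bcl2a1a -2.34, Birc3 -1.06), iron and haem handling (-0.54; Fth1 -1.31), interferon response (-0.48; Ifit3 -1.26), efferocytosis and scavenging (-0.45; Cd36 -0.70), antigen presentation (-0.42; H2-Eb1 -1.70), Kupffer cell maturation (-0.40; Cd207 -1.62, Spic -1.29), dissociation stress (-0.34; Junb -0.77) and macrophage transcription factors (-0.24; Bhlhe40 1.03, Cebpb -0.97) had negative medians. Lipid handling (0.22; Apoe -1.71), glycolysis (0.13; Pgam1 1.07), matrix remodelling and growth factors (0.04; Timp2 1.75, Igf1 1.20) and pro-apoptotic genes (0.01) stood near 0. TMM scaling of the naive pair moved log2 ratios by 0.10.

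Classical monocyte-like and cDC2-like cells of naive mice asked whether IL-4c met the other myeloid classes alike. Both had more RNA for the C-type lectin Mgl2, a marker of IL-4-exposed antigen-presenting cells, and less for Cxcl9, an interferon-induced chemokine that calls T cells. Classical monocyte-like cells also had more Mrc1 and Clec10a, both lectin receptors, and less Inhba, Cxcl2 and the anti-apoptotic Bcl2a1 genes. They differed in cluster as well, with 789 of the 1292 PBS cells in cluster 5 and 837 of the 914 IL-4c cells in cluster 11. cDC2-like cells had more Aqp3, a water and glycerol channel, and Cd209e, a lectin.

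In classical monocyte-like cells, Mgl2 (chromosome 11, 70130329 to 70137550) was at 487 CPM with IL-4c against 7.27 with PBS (log2 6.07, 5.63 to 6.54), Mrc1 at 135 against 9.30 (log2 3.86) and Clec4b1 at log2 3.31. Retnla was at 1209 against 1.86 (log2 9.34), against a background of 506 in plasmacytoid DC-like cells of the naive IL-4c library. Inhba, a subunit of activin, was at 55.4 CPM with PBS (328 UMIs) and had no UMI with IL-4c, at least 117-fold lower. Cxcl9 (chromosome 5, 92321347 to 92328079) was at 60.4 against 1044 (log2 -4.11), Cxcl2 at 13.1 against 542 (log2 -5.37) and Ly6i at 19.9 against 982 (log2 -5.63). Cxcl9 differed between clusters of the naive PBS library as well, at 1546 in cluster 5 and 33.5 in cluster 2, its other main cluster. The inflammatory list had a median of -2.67 (23 of 28 members at least 2-fold lower), the interferon list -1.05 and the IL-4 response list 0.46 (10 of 27 at least 2-fold higher, 7 lower). In cDC2-like cells, Aqp3 was at 171 against 2.03 (log2 6.40, 5.04 to 8.28), Cd209e at log2 3.20 and Mgl2 at 1.90. Cxcl10 (log2 -4.93), Cxcl9 (-4.30) and the interferon-induced GTPase genes Iigp1 (-4.63) and Gbp2 (-3.32) were lower. Their list medians were 0.37 for IL-4 response, -1.27 for inflammatory cytokines and -1.18 for interferon response.

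The comparison of IL-4c with PBS after CCl4 asked how IL-4 acted on macrophages of the injured liver, both the Kupffer-like and the monocyte-derived macrophage-like classes. In both, IL-4c libraries had more RNA for Retnla, Rnase2a, Arg1, Slc7a2, Ear2 and Chil3 and for Ccl8, a monocyte chemokine, and less for Saa3, an acute-phase protein. Monocyte-derived macrophage-like cells also had more Mgl2, the collagen-degrading protease Ctsk and the transferrin receptor Tfrc. They had less of the chemokines Ccl3 and Ccl4, the scavenger receptor Stab1, the lipid carrier Apoe and Gas6, which bridges dying cells to phagocytes. Kupffer-like cells had more RNA for MHC class II genes (H2-Aa, H2-Ab1, Cd74) and less for Marco and the costimulator Cd86.

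Kupffer-like cells after CCl4 were compared across clusters, since 602 of the 731 cells with IL-4c were in cluster 23 and 677 of the 721 with PBS in cluster 1. Cluster 23 was named on weaker grounds than cluster 1. Its mean Kupffer marker log2 fold was 1.34 against 2.95, with 9 against 12 markers at least 2-fold higher. Mmp12, a marker of the monocyte-derived macrophage-like class, was among its 10 leading genes. Whether these cells were resident was not tested. Retnla was at 8481 against 19.8 CPM (log2 8.74, 8.53 to 8.96), Arg1 at 811 against 10.7 (log2 6.25, 5.96 to 6.56), Chil3 at 648 against 49.4 (log2 3.71) and Mrc1 at 454 against 237 (log2 0.94). Rnase2a (log2 8.51), Slc7a2 (4.61), Ear2 (3.05) and the proton pump subunit gene Atp6v0d2 (3.65) were higher too. Saa3 (chromosome 7, 46711998 to 46715700) was at 1.28 against 59.1 (log2 -5.53), and Marco at 895 against 3174 (log2 -1.83). The IL-4 response list had a median of 1.40, with 17 of 26 members at least 2-fold higher, lipid handling 0.48 (Fabp4 2.35) and matrix remodelling 0.42 (Mmp13 2.25, Adam8 1.86). Atp6v0d2 and Fabp4 are also among the 10 leading genes of cluster 9, a macrophage cluster with 1938 cells in this IL-4c library. Scrublet called 2 doublets in that library. Free macrophage RNA and doublets were not set apart from expression for these genes. Inflammatory cytokine genes had a median of -0.86 (Cxcl2 -1.36, Ccl9 1.74), Kupffer cell maturation -0.58 (Timd4 -1.33, Id1 -1.14) and dissociation stress -0.36 (Hspa1a -1.53). Antigen presentation was at 0.21 (H2-Ab1 1.45, H2-Aa 1.44, Cd74 1.36, Cd86 -1.68), anti-apoptotic genes at 0.25, pro-apoptotic genes at -0.09, mitosis and G2/M at -0.02 (0.894 at resolution 2) and S phase at -0.19. Relative to the naive pair, the Retnla log2 ratio was lower by 4.28 and that of Arg1 by 1.03, in part because both were higher with PBS after CCl4. Retnla with PBS was at 19.8 after CCl4 against 2.23 in naive mice (8 UMIs), and with IL-4c at 8481 against 18610. Arg1 with IL-4c was higher after CCl4 than in naive mice. The lower ratios thus do not show a weaker response to IL-4c. The difference of the ratios, taken gene by gene over 23 members of the IL-4 response list, had a median of 0.076, with 1 member at least 1 log2 unit higher after CCl4 and 6 at least 1 lower.

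In monocyte-derived macrophage-like cells after CCl4 (1978 with IL-4c, 1720 with PBS), Retnla was at 8337 against 12.4 CPM (log2 9.40, 9.24 to 9.56), Chil3 at 3815 against 659 (log2 2.53), Arg1 at 1009 against 139 (log2 2.86) and Mrc1 at 326 against 85.3 (log2 1.94). Rnase2a (log2 10.30), Ear2 (4.52), Slc7a2 (4.48), Mgl2 (4.29), Ccl8 (4.08), Ctsk (3.89) and Tfrc (3.16) were higher. Apoe was at 6340 against 27640 (log2 -2.12), and Saa3 (log2 -3.20), Ccl3 (-2.81), Ccl4 (-2.70), Clec4e (-2.68), Stab1 (-2.56) and Gas6 (-2.24) were lower. The IL-4 response list had a median of 1.72 (20 of 30 members at least 2-fold higher), lipid handling 0.64 (Fabp4 2.08), matrix remodelling 0.48 (Igf1 1.33), inflammatory cytokines -1.19 (17 of 30 lower) and interferon response -0.93 (Irf7 -2.04). Efferocytosis and scavenging had a median of -0.30, with Mfge8, another bridging protein, at 2.70 against Stab1 and Gas6. The classical monocyte-like cells were 74 with PBS, spread over clusters 2 (33 cells), 5 (31) and 11 (10), and 468 with IL-4c, 458 of them in cluster 11. Unnamed cluster 7, which also held monocyte genes, is left out, with 674 cells with PBS and 54 with IL-4c. The ratios therefore rest on a small part of the monocyte-like cells of the PBS library. The classical monocyte-like cells had Mgl2 at 531 against 11.4 (log2 5.55), Mrc1 at log2 2.96, Saa3 at -7.27, Cxcl2 at -4.46 and an inflammatory median of -1.69. Their Retnla was at 997 with IL-4c and without a UMI with PBS, at least 146-fold higher, against 459 in plasmacytoid DC-like cells with IL-4c. Their Arg1 ratio (log2 5.15) rested on 1 UMI with PBS and was -0.967 at resolution 2. In all 6 classes compared, plasmacytoid DC-like cells included, Retnla, Chil3, Arg1, Ear2 and Mgl2 were at least 2-fold higher in the CCl4 IL-4c library than in the CCl4 PBS library. Levels in plasmacytoid DC-like cells were low beside those of monocyte-derived macrophage-like cells (Arg1 37.9 against 1009, Chil3 175 against 3815), and free macrophage RNA was not set apart from expression there. AY036118 (log2 2.85 to 3.14), Gm42418 (1.59 to 2.67), Gm26917 (1.85 to 2.27) and Gm10076 (1.51 to 2.38) were also at least 2-fold higher in those 6 classes. They were singled out after their values were seen. For these genes the CCl4 IL-4c and CCl4 PBS libraries differed in each class, which does not tell which library stood apart. Gm10076 was also lower in the CCl4 PBS than in the naive PBS library (log2 -3.795 to -3.243). In cDC2-like cells, of which 227 of 262 with PBS were in cluster 6 and 432 of 463 with IL-4c in cluster 10, Aqp3 (log2 4.80), Cd209e (3.25) and Hfe (2.19), an iron regulator, were higher and Ccl17 (-6.28), Cxcl2 (-4.18) and Lyz2 (-3.53) lower, with list medians of 1.08 for IL-4 response and -1.59 for inflammatory cytokines. Their Retnla, at 465, was at the plasmacytoid DC-like level.

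**Figure D3:**
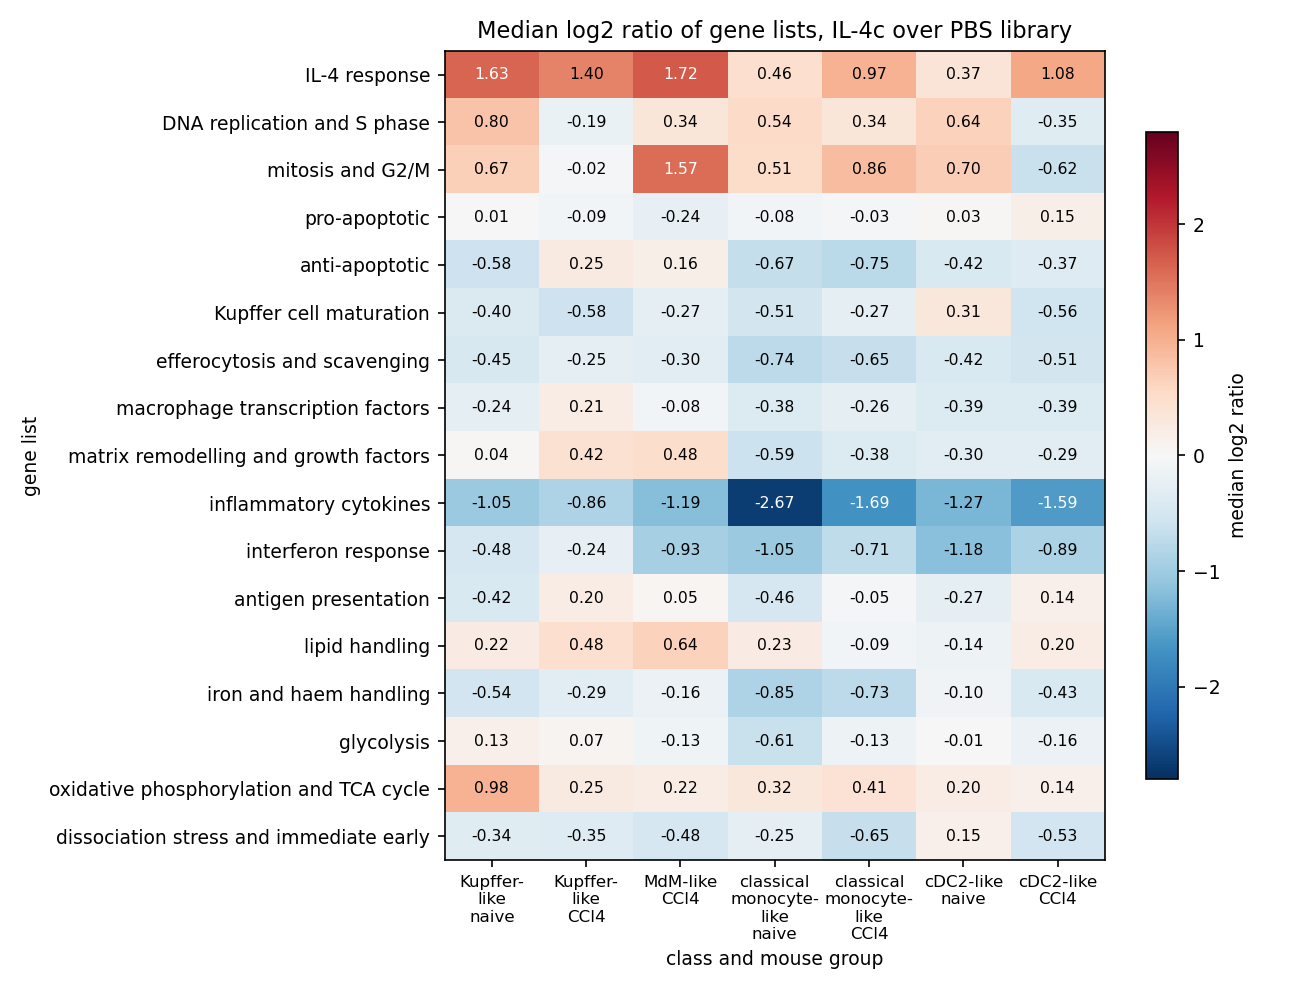
Colour gives the median log2 ratio of IL-4c over PBS of the measured members of 17 gene lists (y axis) in 7 combinations of cell class and naive or CCl4-treated mice (x axis; MdM-like, monocyte-derived macrophage-like). The IL-4 response list is positive in all of them, from 0.37 in naive cDC2-like cells to 1.72 in monocyte-derived macrophage-like cells after CCl4, and the inflammatory list is negative in all.

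The comparison of CCl4 with naive mice among PBS libraries asked how injury without IL-4c related to the myeloid cells. Its reference, the naive PBS library, was also that of the naive IL-4c comparison. That library held 789 cells of the inflammatory monocyte-like cluster 5, against 28, 31 and 7 in the others. Lower interferon response and antigen presentation RNA in either comparison therefore cannot be told apart from a high level in that library. Kupffer-like cells after CCl4 had more RNA for the fatty-acid binding protein Fabp5, the acute-phase protein Saa3, the platelet-type chemokine Pf4, the lipid receptor Cd36 and the lysosomal protease Ctsd. They had less RNA for MHC class II genes and for the interferon-induced genes Gbp2b, Gbp5 and Serpina3g. Monocyte-derived macrophage-like cells had more Chil3, Fabp4, Lpl and Hmox1, genes of lipid uptake and haem breakdown, and less of the lectin Cd207 and of MHC class II genes, but the class was mostly cluster 8 after CCl4 and cluster 13 in naive mice. Kupffer-like cells differed in cluster too, with 677 of 721 in cluster 1 after CCl4 and 536 of 594 in cluster 0 in naive mice. Fabp5, Saa3 and Pf4 are also among the 10 leading genes of cluster 8, and Scrublet called 0 doublets in the CCl4 PBS library. Free macrophage RNA and doublets were not set apart from expression for these genes.

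In Kupffer-like cells, Fabp5 (chromosome 3, 10012548 to 10016607) was at 220 CPM after CCl4 against 11.2 (log2 4.30, 3.85 to 4.79), Saa3 at log2 3.82, Pf4 at 3.15, Cd36 at 2.36 and Ctsd at 1.98. H2-Aa (chromosome 17, 34282744 to 34287823) was at 295 against 4836 (log2 -4.04, -4.10 to -3.98), while plasmacytoid DC-like cells held it at 3016 and 2839. H2-Eb1 (log2 -4.23), H2-Ab1 (-3.86), Cd74 (-3.85) and Gbp2b (-6.01, 4.30 against 277) were lower. Retnla was at log2 3.15, Chil3 at 2.30, Arg1 at 1.93 and Mrc1 at -0.92. Antigen presentation had a median of -1.27 (10 of 19 members at least 2-fold lower), interferon response -1.11 (Ifit2 -2.15, Stat1 -1.71), anti-apoptotic genes -0.81 (Birc3 -1.78), dissociation stress -0.71 (Hspa1b -3.23), mitosis and G2/M 0.70 (Cdca3 1.45, Ccnb2 1.45) and matrix remodelling 0.62 (Ctsd 1.98, Lgals3 1.42). The IL-4 response list was at -0.03. In monocyte-derived macrophage-like cells, Chil3 was at log2 4.71, Fabp4 at 3.49, Lpl at 2.94, Hmox1 at 2.83, Cd207 at -5.68 and H2-Aa at -3.83. Their antigen presentation median was -1.40, interferon response -0.99 and iron and haem handling 1.01. Their Retnla log2 ratio was -4.62 and turned to 2.14 when cells above the common UMI floor were clustered again, and 445 of the 447 naive UMIs sat in the 37 naive cells of cluster 8.

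Classical monocyte-like cells after CCl4, 74 against 1292 in naive mice, had more Fabp4 (log2 2.52), Ctsd (1.98), Chil3 (1.48) and Apoe (1.38) and less Ccl5 (-4.58) and H2-Q7 (-3.34), an MHC class I gene. The 674 CCl4 PBS cells of unnamed cluster 7 were not among the 74. cDC2-like cells had more Cxcl2 (log2 3.41), Ctsd (3.09), Cd14 (2.64), a lipopolysaccharide co-receptor, and Lyz2 (1.73), and less Iigp1 (-5.06), Cxcl9 (-4.16) and the sterol synthesis gene Hmgcs1 (-3.61). Their interferon response median was -0.81. The median log2 ratio of all genes in this contrast was -0.13 in Kupffer-like, -0.18 in monocyte-derived macrophage-like and -0.12 in cDC2-like cells. In all 6 classes compared, the CCl4 PBS library had at least 2-fold more RNA for Chil3, Spp1, Ctsd and Trem2, and at least 2-fold less for 29 genes, among them Gm10076 and Gstp1, all singled out after their values were seen. The first 4 are genes of the macrophages that fill the CCl4 library, and plasmacytoid DC-like cells held little of them (Spp1 109 against 7011 CPM in monocyte-derived macrophage-like cells, Trem2 53.0 against 1157), so free RNA was not set apart from expression. CCl4 cannot be set apart from any technical difference between the naive and the CCl4 libraries either.

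Division of macrophages was compared because growth of reparative macrophages under IL-4 is part of the study's question. Kupffer-like cells of naive mice had more mitotic RNA after IL-4c than after PBS, including Top2a, a topoisomerase of dividing cells, and Mki67, a proliferation marker. After CCl4, Kupffer-like cells with mitotic RNA were already more frequent with PBS, and with IL-4c the share was a little higher. Monocyte-derived macrophage-like cells with mitotic RNA were more frequent with IL-4c than with PBS after CCl4. That difference was smaller once cycling cells were kept with their type, and the mitosis and S phase lists then hardly differed. In that clustering, cDC1-like and cDC2-like cells with mitotic RNA were also more frequent with IL-4c, in naive mice and after CCl4.

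The share of Kupffer-like cells with at least 1 UMI of the 12 mitotic genes among 1000 UMIs was 10.1% (7.80 to 12.8%), 23.8% (20.9 to 26.8%), 24.4% (21.3 to 27.7%) and 28.9% (25.6 to 32.3%). By the planned count, the log2 ratio of the Kupffer-like share with IL-4c to that with PBS after CCl4 was 0.218, and 0.496 at resolution 2. In plasmacytoid DC-like cells the share by the 12 mitotic genes was 3.13, 3.65, 1.59 and 4.11%. Their median depths were 4191, 4583, 4312 and 3728 UMIs against 5370, 7726, 11477 and 8081 in Kupffer-like cells. Top2a (chromosome 11, 98992943 to 99024189) in Kupffer-like cells was at 60.3, 118, 64.0 and 66.6 CPM and Mki67 (chromosome 7, 135689784 to 135716361) at 38.5, 52.9, 38.2 and 41.6, so both were alike in the PBS libraries although the share of cells with mitotic RNA was not. In monocyte-derived macrophage-like cells clustered without genes that follow the cell cycle, the share was 22.4% (20.5 to 24.4%) with PBS and 31.2% (29.1 to 33.3%) with IL-4c after CCl4, with Mki67 at 38.8 and 40.1 and Top2a at 81.3 and 99.2. In the main clusters, cluster 24 had taken cycling cells of the PBS library out of the class. There the share was 11.9% with PBS and 31.1% with IL-4c, the mitosis and G2/M median was 1.57, Mki67 was at log2 1.76 and Top2a at 2.22. Clustered without genes that follow the cell cycle, the mitosis and G2/M median was 0.083 and the S phase median -0.071. The share of classical monocyte-like cells in that clustering was 4.76, 8.22, 3.57 and 22.3%, and that of cDC2-like cells was 16.2% with PBS and 20.7% with IL-4c after CCl4.

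**Figure D4:**
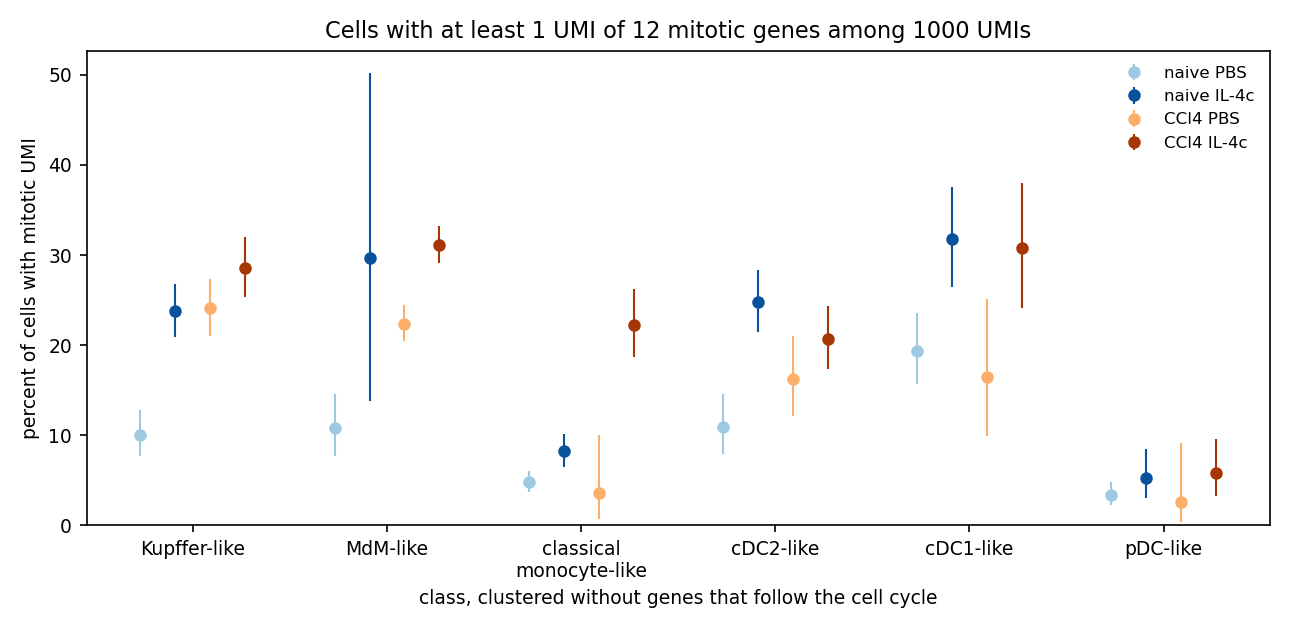
Percent of cells with at least 1 UMI of 12 mitotic genes among 1000 UMIs (y axis) in each class (x axis) of the 4 libraries, clustered without genes that follow the cell cycle, with exact binomial 95% bars. Monocyte-derived macrophage-like cells stand at 22.4% with PBS and 31.2% with IL-4c after CCl4, and plasmacytoid DC-like cells, the background, are at 5.83% or less in all libraries.

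Apoptosis genes of classical monocyte-like cells were compared because monocyte death under IL-4 is part of the study's question. Pro-apoptotic genes as a group hardly differed between IL-4c and PBS, while RNA for the anti-apoptotic Bcl2a1 genes, which hold back mitochondrial cell death, was lower with IL-4c. The death receptor gene Fas was lower and the executioner caspase gene Casp6 higher. These ratios compare different clusters as well as treatments. In naive mice 789 of the 1292 PBS cells were in cluster 5 and 837 of the 914 IL-4c cells in cluster 11. After CCl4, 74 PBS cells stood against 468 with IL-4c, without the 674 PBS cells of unnamed cluster 7. A change of these genes within the same kind of monocyte was not shown. The pro-apoptotic median was -0.08 in naive mice (Fas -2.29, Casp6 1.71) and -0.03 after CCl4 (Fas -2.07, Casp6 1.89), at percentiles 13.7 and 19.0 of random lists. The anti-apoptotic median was -0.67 (Bcl2a1b -4.11, Bcl2a1a -3.64, Bcl2a1d -3.00) and -0.75 (Bcl2a1d -4.41, Bcl2a1a -4.31, Bcl2a1b -3.51). Cell death itself was not measured, and cells that had died would not be among the live sorted cells.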

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

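The test of a shared response to CCl4 and the test of free globin RNA were chosen after the result was seen, as was the rule that reads the pseudogene test.

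In Kupffer-like cells, anti-apoptotic genes had a median log2 ratio of IL-4c over PBS of -0.58 in naive mice and 0.25 after CCl4, a difference of 0.825, and antigen presentation genes stood at -0.42 and 0.21, a difference of 0.629. In cDC2-like cells, 3 lists went the other way: DNA replication and S phase genes stood at 0.64 in naive mice and -0.35 after CCl4 (difference -0.987), mitosis and G2/M genes at 0.70 and -0.62 (difference -1.32), and dissociation stress genes at 0.15 and -0.53 (difference -0.685). Each was singled out because its sign was opposite in the naive and the CCl4 pair of libraries. With 1 library per group, none of these 5 differences was tested. The cDC2-like mitosis median after CCl4 was 0.452 when cycling cells were kept with their type, and in naive mice it was -0.837 with each library clustered on its own.

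Every one of 6 classes held at least 2-fold less RNA of 29 genes in the CCl4 PBS library than in the naive PBS library, among them Gm10076 and Gstp1, which were singled out after their values were seen. If reads of near-identical copies had been assigned differently in the libraries, annotated pseudogenes would be lower as a set, and the highest of their 6 class medians was -0.271, in Kupffer-like cells. That value met the bound written in advance for excluding this explanation (above -0.5), but the 25 pseudogenes are a wider set than genes with near-identical copies, the middle 50% of them in Kupffer-like cells ran from -1.52 to 0.18, 9 of them were at least 2-fold lower there, and the other medians went down to -1.32, so it was not taken as excluding it. A response to CCl4 shared by every class is a candidate explanation too. Of the 29 genes, 24 are not annotated as pseudogenes, but that does not show that they lack near-identical copies, so this count decides nothing. The explanations cannot be told apart, because CCl4 goes together with the library in the PBS pair and in the IL-4c pair. Between the IL-4c libraries, the pseudogene medians of CCl4 over naive ran from -0.948 in cDC2-like to -0.53 in plasmacytoid DC-like cells. Gm10076 also differed between the CCl4 IL-4c and CCl4 PBS libraries, by log2 1.51 to 2.38 in all 6 classes, so its level does not go with CCl4 alone.

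Kupffer-like cells of the naive IL-4c library held 7840 globin UMIs against 19, 10 and 9 in the naive PBS, CCl4 PBS and CCl4 IL-4c libraries. Free globin RNA would reach every class at a like level, but Hbb-bs in Kupffer-like cells, at 495 CPM, was 5.74 times its level in the highest other class, cDC1-like cells. That ratio cannot exclude free globin RNA at a lower level, because few barcodes set the Kupffer-like value. In cDC2-like, classical monocyte-like and plasmacytoid DC-like cells of this library Hbb-bs was alike, at 5.55, 4.73 and 5.75. In the other libraries these classes held 0.516 or less. The 5% of Kupffer-like cells with the most globin UMIs held 99.5% of them, and 4901 were in 1 barcode, which is consistent with a few droplets that also caught a red cell or a precursor. Uptake of red cells by Kupffer-like cells would also place globin RNA in few cells and was not tested.

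Retnla RNA was found in classes other than macrophages in the IL-4c libraries. In plasmacytoid DC-like cells of the naive IL-4c library it was at 2.72% of its Kupffer-like level, within the range of 10 Kupffer markers (median 2.34%, 1.42 to 41.2%), as free Kupffer-like RNA would give, although 1 marker, Cdh5, sets the upper end and makes the test weak. Classical monocyte-like cells held 2.39 times the plasmacytoid DC-like level, against a median of 1.19 for the Kupffer markers. The markers ranged from 0.0475, set by Cdh5, to 23.8, set by Adgre1. The other markers ran from 0.729 to 1.49, below Retnla, but setting those apart was not planned and rests on 1 library. By the bounds written in advance, Retnla expression by the monocyte-like cells and free RNA alone cannot be told apart.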

How the results depend on the processing

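The alternatives with a common UMI floor, with the highest 5% of Scrublet scores left out, clustered without genes that follow the G2/M list, without cluster 5, with cluster 7 counted as classical monocyte-like, and with 12 mitotic genes were chosen after seeing the data; the others were fixed before the data were examined. Gene lists and genes were recomputed for Kupffer-like, monocyte-derived macrophage-like, classical monocyte-like and cDC2-like cells, a limit set after a first run over all classes, so the ratios given over all compared classes were not recomputed for cDC1-like and plasmacytoid DC-like cells. No paired analysis was possible because each group had 1 library and the labels pair no mice. Values below are log2 ratios with the reported value after "for"; a share ratio is that of a class's share. Below, above the floor means that cells above the common UMI floor were also clustered and named again. The cause was not tested for any of them.

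Over all alternatives, 2186 of 2669 gene list medians stayed within their counting interval, 466 moved beyond it and 17 turned against a called sign. For genes these were 3045, 711 and 11 of 3767, for shares 210, 56 and 3 of 269, and for cycling shares 218, 42 and 0 of 260. A share, cycling share or gene was called at a difference of at least 2-fold with an interval that left out 1. A list median was called at an outer percentile of the random lists. Sign changes of values not called stand among the first and second counts, so the third count does not hold every sign change. The IL-4 response median stayed positive throughout, from 0.951 to 1.94 in naive Kupffer-like cells, 1.23 to 1.88 in Kupffer-like cells after CCl4 and 1.60 to 2.45 in monocyte-derived macrophage-like cells, and the patrolling monocyte-like share ratio in naive mice stayed between -3.28 and -2.65 over the alternatives, which cluster the cells again or count all kept cells. With the reported classes kept and only cells above the common UMI floor counted, it was -3.67, the 12.8-fold of the results. A minimum of 1000 UMIs removed no cell. Depth limits classes with few cells: 74 classical monocyte-like and 63 plasmacytoid DC-like cells after CCl4 with PBS, and 26 monocyte-derived macrophage-like cells with IL-4c in naive mice.

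Classical monocyte-like shares depended on the clustering. For IL-4c over PBS in naive mice the share ratio was -4.05 without a cell filter, -1.60 at resolution 2, -1.33 with the gene lists among the clustering genes, -0.986 with each library clustered on its own, -0.029 of all kept cells, 0.746 above the common UMI floor and 1.51 without cluster 5, for 0.198. After CCl4 it was -2.61 without a cell filter, -0.795 at resolution 2, -0.682 with cluster 7 counted in, 1.43 with the lists in, 2.96 above the floor and 3.26 without cluster 5, for 2.498. For CCl4 over naive it was -8.11 with each library on its own, -4.61 without a cell filter, -3.54 with the lists in, -3.32 without cluster 5, -1.04 at resolution 2 and -0.582 with cluster 7, for -3.90. The share ratio of cluster 7 after CCl4 was -0.599 with each library on its own, -2.73 without the highest Scrublet scores, -2.739 at resolution 2, -2.74 at resolution 0.5 and -4.49 above the floor, for -3.81.

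For monocyte-derived macrophage-like cells after CCl4, the share ratio of IL-4c over PBS was -0.363 without the highest Scrublet scores, -0.313 at resolution 0.5, -0.214 with the lists in, 0.184 at resolution 2, 0.386 above the floor and 0.627 with each library on its own, for 0.039. For CCl4 over naive it was 0.942 with each library on its own, 2.25 at resolution 2, 2.87 at resolution 0.5, 2.90 without the highest Scrublet scores, 2.92 above the floor and 6.52 with the lists in, for 2.56. The naive cDC2-like share ratio was 0.733 with each library on its own, 0.885 of all kept cells, 1.31 at resolution 0.5, 1.503 without G2/M-following genes and 1.57 without the highest Scrublet scores, for 1.11. The naive plasmacytoid DC-like one was -0.995 with each library on its own and -0.936 of all kept cells, for -0.710.

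In monocyte-derived macrophage-like cells after CCl4 (IL-4c over PBS) the mitosis and G2/M median was 0.083 without G2/M-following genes, 0.189 at resolution 0.5, 0.228 without the highest Scrublet scores, 0.696 with the lists in, 1.08 with Scrublet calls kept, 1.23 at resolution 2, 1.66 without a cell filter and 1.73 with every cell weighted equally, for 1.57. For CCl4 over naive it was 0.189 above the floor, 0.358 at resolution 0.5, 0.437 without G2/M-following genes and 0.782 without the highest Scrublet scores, for -0.943; Mki67 there was 0.219 without G2/M-following genes, 0.169 at resolution 0.5 and 0.626 without the highest Scrublet scores, for -1.44, and Top2a 0.135 above the floor and 0.512 without those scores, for -1.91. In naive Kupffer-like cells the median was 0.567 without a cell filter, 0.75 with median-of-ratios factors, 0.772 with TMM factors, 2.27 at resolution 2 and 3.24 with each library on its own, for 0.671, and after CCl4 it was 0.104 with cells weighted equally and 0.894 at resolution 2, for -0.024. In cDC2-like cells it was 0.452 without G2/M-following genes after CCl4, for -0.621, and with each library on its own -0.837 in naive mice, for 0.699, and -0.056 for CCl4 over naive, for 0.902. In classical monocyte-like cells after CCl4 it was -0.037 with members of at least 1 UMI, for 0.864.

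The ratio of the planned cycling share in naive Kupffer-like cells was 0.132 not thinned, 0.285 thinned to 2000 UMIs, 0.378 with at least 2 UMIs, 1.001 at resolution 2, 1.23 with 12 mitotic genes and 1.76 with each library on its own, for 0.721; after CCl4 it was 0.496 at resolution 2, for 0.218. In monocyte-derived macrophage-like cells after CCl4 it was 0.004 not thinned, 0.271 thinned to 2000 UMIs, 0.336 without G2/M-following genes, 0.347 with at least 2 UMIs, 0.383 at resolution 0.5, 0.446 with the lists in, 0.459 without the highest Scrublet scores and 1.39 with 12 mitotic genes, for 0.623.

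The IL-4 response median in naive Kupffer-like cells was 0.951 with members of at least 1 UMI and 1.351 without a cell filter, for 1.63. After CCl4 it was 1.23 with members of at least 1 UMI and 1.884 at resolution 2, for 1.40. In monocyte-derived macrophage-like cells it was 1.89 without the highest Scrublet scores, 1.93 without G2/M-following genes, 1.99 above the floor, 2.06 at resolution 2 and 2.45 with each library on its own, for 1.72. Other lists of monocyte-derived macrophage-like cells that turned were Kupffer cell maturation (0.066 above the floor and 0.105 at resolution 2, for -0.272), S phase (-0.071 without G2/M-following genes, for 0.340) and, for CCl4 over naive, glycolysis (-0.166 with each library on its own, for 0.537). In classical monocyte-like cells these were, at resolution 2, interferon response after CCl4 (0.080, for -0.712) and lipid handling in naive mice (-0.099, for 0.233); with the lists in, transcription factors after CCl4 (0.020, for -0.260), interferon response for CCl4 over naive (0.101, for -0.242) and pro-apoptotic genes in naive mice (0.098, for -0.079); and with members of at least 1 UMI, inflammatory cytokines for CCl4 over naive (0.155, for -0.208).

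Other genes that turned were, in classical monocyte-like cells, Ccnd1 in naive mice (-1.46 with the lists in and -0.131 at resolution 2, for 2.49), Arg1 after CCl4 (-0.967 at resolution 2, for 5.15) and Ifit1bl1 for CCl4 over naive (-0.608 at resolution 2, for 1.99). For CCl4 over naive, Retnla in monocyte-derived macrophage-like cells was 2.14 above the floor, for -4.62, and Cxcl10 in cDC2-like cells 0.131 without the highest Scrublet scores, for -2.63.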

Other observations

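The clusters described here were singled out after their values were seen, and no test was run on them. The naive PBS library held a monocyte-like population with strong inflammatory RNA. Cluster 5, led by Ly6i, Cxcl9 and Cxcl10, chemokine genes that interferon gamma induces, and by the acute-phase gene Saa3, held 789 naive PBS cells against 28, 31 and 7 in the naive IL-4c, CCl4 PBS and CCl4 IL-4c libraries. Cxcl10 was at 1016 CPM in its naive PBS cells, against 77.2 in cluster 2 and, with IL-4c, 23.7 in cluster 11. For 2 interferon-induced genes picked for their values, the level was highest in the naive PBS library in another class. Gbp2b, a guanylate-binding protein gene, was at 277, 129, 4.30 and 7.04 CPM in Kupffer-like cells, and Iigp1, a GTPase gene against intracellular microbes, was at 62.1, 37.7, 3.31 and 18.4 in plasmacytoid DC-like cells.

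Lymphoid cells were present although the gate excluded CD3+ and NK1.1+ cells. Cluster 14, with Gzma and Nkg7, genes of cytotoxic granules, and Cd3g, of the T cell receptor complex, held 54, 75, 6 and 67 cells. Its naive IL-4c cells had Gzma at 4777 CPM and Mcpt8, a basophil protease gene, at 473, so it mixes cell types. Plasma cell-like cells, with Jchain and Mzb1, numbered 19, 0, 0 and 10, and hepatocyte-like cells 12, 8, 0 and 0. Cycling cells in cluster 20 numbered 46, 125, 3 and 114. A small set of 37 naive PBS cells lay in cluster 8, the main macrophage cluster of the CCl4 PBS library, with Spp1, a matrix-linked cytokine gene, at 4508 CPM against 7035 in the CCl4 PBS cells, and with Retnla at 2355 CPM.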
